A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

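Ribosome profiling measures translation by sequencing the stretches of mRNA that ribosomes shield from nuclease, beside fragments of the mRNA itself. Per the labels' protocols, the budding yeast strain BY4741, a haploid laboratory strain deleted for HIS3, LEU2, MET15 and URA3, was grown at 30 °C in rich YEPD medium to an optical density of 0.6 to 0.7. Cells were taken there or after 20 min in minimal medium with no amino acids. All cultures received cycloheximide, which arrests elongating ribosomes, at 100 ug/ml for 2 min. Footprints came from lysates digested with 150 U of RNase I for 1 h and from the monosome peak of a sucrose gradient, and polyadenylated mRNA was broken in mild alkali at 95 °C. Pieces of about 30 nt were tailed with poly-A, converted to circular DNA and sequenced.

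The files hold 8 libraries in 4 groups of 2: footprints from rich medium, footprints from starved cells, mRNA from rich medium and mRNA from starved cells. Group and replicate number were taken from the labels. The name of 1 rich footprint table gives replicate 1 where the label gives 2, and the label was kept, since its counts were nearest to the alignments of replicate 2. The series design names biological replicates, but the labels say nothing of separate cultures, so p-values measure the spread between these samples, which may be partly technical. Per the file headers, replicate 1 and replicate 2 of each group were read in different sequencing runs, and each number holds all 4 groups. List medians and efficiency changes were therefore also taken within each replicate number.

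Per the file headers, the authors took features and the reference from the Saccharomyces Genome Database as of 2008-06-22 and UTRs from a transcript map of Nagalakshmi and colleagues (2008). Reads left after removal of ribosomal RNA were aligned to the chromosomes with SOAP together with a tail of 20 A, with 32 as the setting for the smallest confident match. The deposited counts are whole numbers of reads per feature, not normalised. The deposited RPKM values give each count per kilobase of the feature and per 1000000 coding reads of the library. The same tables hold a deposited density signal in reads per kilobase, used to check the other columns. The deposited alignments give each distinct read with its number of copies, its position and an alignment score, which per the file headers counts matches to the reference plus the tail. How the authors assigned reads shared by near-identical genes is not given in the sources used here. Values of genes with a close copy, such as most ribosomal protein genes, SER3 and SER33, SAM1 and SAM2, HXK1 and HXK2, HTB1 and HTB2 or the IMD genes, are uncertain for that reason. The count of 13748 features per file was the same in each library. It includes 5295 nuclear coding sequences, 3523 5' UTRs, 4592 3' UTRs and 225 introns, and all 5295 coding sequences were paired with a symbol through a table of gene names of assembly R64, which was used for names alone. Each listed coding sequence has at least 1 read in replicate 2 of the mRNA from rich medium. These hold 69.9% to 84.5% of the deposited coding totals, and other genes were not analysed. Listed are 58 of 137 cytosolic ribosomal proteins, 8 of 13 elongation and termination factors and 11 of 16 glycolysis genes.

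Changes per gene were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test, with library sizes set to the deposited totals of coding reads, TMM factors and edgeR's filter on low counts, which left 5073 genes. A single fit held all 8 libraries as 4 group means, with 4 residual degrees of freedom, a common dispersion of 0.0139 (a biological coefficient of variation of 0.118) and 15.1 prior degrees of freedom. Translational efficiency is the ratio of footprints to mRNA, and its change was tested in the same fit as an interaction: the footprint change minus the mRNA change. Each kind of library is scaled to its own total, so a change shared by all genes is not visible, and efficiencies are relative to the mean gene. Adjusted p is the Benjamini-Hochberg value over the genes tested, and a gene was called at an adjusted p under 0.05. Changes are log2 fold changes, starved over rich, with their standard errors (SE), and each group has n = 2. TMM factors were between 0.582 and 0.847 for footprints and between 1.328 and 1.492 for mRNA. An exact permutation test of 2 against 2 goes no lower than p = 0.33, 2-sided, so values per library are given without a test.

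There were 33 gene lists: cytosolic ribosomal proteins, ribosome biogenesis factors, subunits of RNA polymerases I and III, translation initiation factors, elongation and termination factors, aminoacyl-tRNA synthetases, regulators of general amino acid control, the biosynthesis of arginine, lysine, histidine, branched-chain and aromatic amino acids, methionine with sulfur assimilation, the aspartate, threonine, serine, glycine and asparagine group, the glutamate, glutamine and proline group, purines, amino acid permeases, targets of nitrogen catabolite repression, genes induced in the environmental stress response, the proteasome, autophagy and vacuolar proteases, glycolysis and fermentation, the nuclear-encoded respiratory chain, mitochondrial ribosomal proteins, ergosterol biosynthesis, phosphate starvation genes, the iron regulon, histones, genes with characterised upstream open reading frames, MATa-specific genes, genes of the other mating type, sporulation genes and the genes deleted in the strain. The 31 lists with enough tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. List p-values were adjusted over the 31 lists within a contrast. With an estimated correlation no list was called in any of the 3 contrasts, and that value is printed beside each call. Members were also counted with p adjusted over the list alone.

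Genes were named by a rule: for each contrast, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 100 reads per mRNA library whose starved libraries both lay on the same side of both rich ones; from each list up to 4 members with the smallest p and the strongest member against the majority; GCN4, CPA1, GCN2 and the deleted genes always; the 6 highest and 6 lowest efficiencies in rich medium; and the 5 highest and 5 lowest leader changes. Most members that make up a count of 5 or fewer were named as well, and those were chosen after their values were seen. Groups, tests, lists, the naming rule and the alternatives listed at the end were fixed before the data were examined. Against a group with no read, a fold was taken over a floor of 3 reads in that group and is given as a lower bound. Bounds and counting intervals cover counting error alone, since the reads carry no molecular identifiers.

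Positions of reads came from the deposited alignments. No genome of that build was used here, so bases were rebuilt from the reads themselves at 9820568 positions, and 4498 of the 5295 coding sequences were located as an open frame of the listed length whose rebuilt counts, scaled by their median ratio to the deposited ones (1.16), deviated in sum over the libraries by no more than 10% of the deposited reads plus 3 reads. A read was assigned to the base 12 nt from its 5' end. A leader was the window of 150 nt upstream of the start codon, complete for 4473 genes, and leader counts were tested with edgeR with the library sizes and factors of the coding sequences. Reading frame, read length and the density of footprints along coding sequences of at least 400 codons were computed from the same reads with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

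The test was checked on simulated counts drawn from the real means with 200 genes changed. At a 2-fold change it recovered 85.1% of the changed genes for mRNA, 73.1% for footprints, 41.8% for efficiency and 1.5% for leader footprints. At 4-fold it recovered 100%, 97%, 93.9% and 7.6%. Alternatives were DESeq2's size factors, library totals without TMM factors, DESeq2 1.42.0 in place of edgeR, no filter, a filter of 100 reads over the mRNA libraries, the libraries of a comparison alone, a replicate block, counts rebuilt from the alignments without the codons next to start and stop, other windows and offsets for leaders, and leaving out each library in turn. A few more were added after the data were seen.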

Results

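Ribosome footprints and mRNA fragments were sequenced from yeast growing in rich medium and from yeast starved of amino acids for 20 min, with 2 libraries per group. The deposited totals of coding reads were 1698134 and 3151832 for footprints from rich medium (replicates 1 and 2), 788626 and 2040043 for footprints from starved cells, 1451219 and 3541965 for mRNA from rich medium and 857584 and 2375965 for mRNA from starved cells.

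Replicates were close for genes with at least 100 reads over both. The SD of the log2 ratio between replicates was 0.298 for footprints in rich medium (3246 genes), 0.345 for footprints in starved cells (2799), 0.256 for mRNA in rich medium (4538) and 0.341 for mRNA in starved cells (4261), where counting error alone would give 0.189, 0.212, 0.170 and 0.2.

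Footprints carried the codon pattern of moving ribosomes and mRNA fragments did not. Among 28-nt footprints the 5' end fell on the first base of a codon in 74.05% and 62.63% of reads from rich medium and in 74.13% and 54.27% from starved cells. In the mRNA libraries that share was between 31.76% and 33.99%. Footprints were denser near the start of coding sequences than further in. Relative to codons 200 to 400, the density over codons 1 to 30 was 3.31 and 3.41 in rich medium and 3.88 and 5.25 in starved cells, with bootstrap errors over genes between 0.058 and 0.108, and mRNA gave values between 0.861 and 0.930. Both starved values near the start lay above both rich ones (exact p = 0.33, the lowest for 2 against 2).

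**Figure D1:**
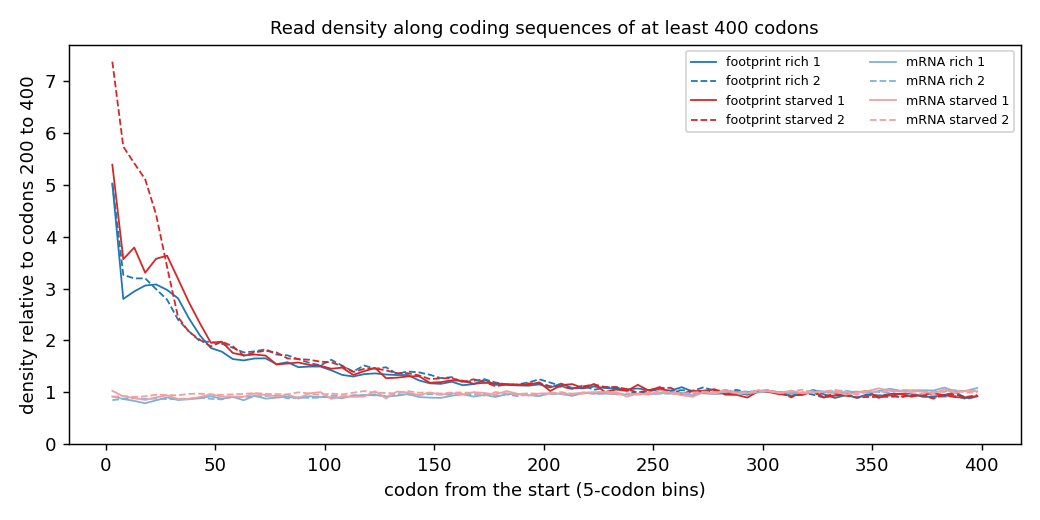
Density of reads per codon relative to codons 200 to 400, in bins of 5 codons from the start codon, with each gene weighted equally and a line per library. Footprint lines fall along the coding sequence, with mean densities over codons 1 to 30 of 3.36 in rich medium and 4.56 in starved cells, while the mRNA lines stay near 1.

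First mRNA levels were compared, starved over rich. Transcripts for sulfate uptake and methionine synthesis rose together: of 25 genes on the list 24 rose and none fell. Their median log2 change was 3.83 (3.73 within replicate 1 and 4.07 within replicate 2). SUL1, a sulfate permease, rose by 5.97 on the log2 scale (SE 0.28, adjusted p = 8.33e-12), and MET3, the ATP sulfurylase that activates sulfate, rose by 5.32 (SE 0.20, adjusted p = 1.1e-12). MET16, which reduces the activated sulfate, rose by 4.01 (SE 0.19), and SAM2, an S-adenosylmethionine synthetase, rose by 3.83 (SE 0.19). STR3 at 5.48, the regulator MET32 at 4.66 and MET2 at 4.47 were also among the 8 largest increases, and MET7, which adds glutamate residues to folate, stood at -0.11 (adjusted p = 0.584). All 24 were called when adjusted over the list alone, and the list differed from other genes by camera (adjusted p = 6.76e-48, adjusted p = 0.211 with an estimated correlation). The other largest increases were HSP12, a small membrane-bound stress protein, at 6.65 (SE 0.26, adjusted p = 1.1e-12), SEO1, a permease, at 5.74 and the hexokinase HXK1 at 5.05.

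Transcripts for making ribosomes fell. All 113 tested ribosome biogenesis factors fell, with a median of -2.03 (-1.60 within replicate 1 and -2.41 within replicate 2). So did all 58 tested of 137 cytosolic ribosomal proteins, with a median of -1.30 (-1.26 and -1.41). Of 20 RNA polymerase I and III subunits 19 fell (median -1.69). UTP23, a factor of the small ribosomal subunit's assembly, fell by 3.95 on the log2 scale (SE 0.28), and RRS1 fell by 3.28 (SE 0.22). RPA135, the second largest subunit of RNA polymerase I, fell by 2.81 (SE 0.20), and RPL22B fell by 2.52 (SE 0.19), these 4 at an adjusted p of 2.29e-09 or less. The exception among the polymerase subunits was RPA14 at -0.05 (adjusted p = 0.919). Counts adjusted over the list alone were the same 113, 58 and 19. Camera gave adjusted p values of 9.41e-48, 5.18e-24 and 2.55e-13, and with an estimated correlation the 3 lists had an adjusted p = 0.319, 0.25 and 0.319. TOD6, a repressor of ribosome biogenesis genes, fell by 3.63 and the RNA helicase DBP2 fell by 3.74. Among the other large decreases were genes of amino acid breakdown and metal uptake. CHA1, the serine deaminase, fell by 5.29 (SE 0.23, adjusted p = 3.92e-12), and ARO10 and ARO9 of aromatic amino acid catabolism fell by 4.73 and 4.10. The iron reductase FRE1 fell by 3.95 and the copper transporter CTR1 fell by 3.53.

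Translation factors moved less. Of 24 initiation factors 16 fell and TIF4632, an eIF4G, rose by 0.66 (SE 0.19, adjusted p = 0.0067). This call was lost without rich mRNA replicate 2 (0.55, adjusted p = 0.0999). TIF3, an eIF4B, fell by 1.33 and TIF5, the eIF5, fell by 1.09. The list's median was -0.69, the counts were 16 and 1 when adjusted over the list alone, and camera gave an adjusted p = 0.00309, or adjusted p = 0.505 with an estimated correlation. Of 8 elongation and termination factors 5 fell, led by RLI1 at -1.68 and YEF3 at -1.64, while CAM1 rose by 0.97 (5 and 1 adjusted over the list alone; median -0.66; adjusted p = 0.108, or 0.0487 without rich mRNA replicate 1). Of 18 aminoacyl-tRNA synthetases 7 fell, led by MES1 at -1.38 and GLN4 at -1.36, and 3 rose (GUS1 at 0.86, DPS1 at 0.51 and FRS2 at 0.48), with the same counts adjusted over the list alone (median -0.28, adjusted p = 0.232). Among 13 regulators of general amino acid control 6 fell, led by GCN3 at -0.89, and the same 6 and 1 passed when adjusted over the list alone (median -0.34, adjusted p = 0.204). GCN20 rose by 0.40 (adjusted p = 0.0447), which did not pass without any of the 4 mRNA libraries in turn (0.35, 0.46, 0.41 and 0.39, with adjusted p between 0.0859 and 0.195).

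Amino acid biosynthesis outside the sulfur pathway was mixed. Arginine genes had 5 of 8 higher and 2 lower, ARG8 at -0.86 and CPA1 at -1.15. ARG1, argininosuccinate synthetase, stood at 2.99 (SE 0.25) and ARG4 at 1.63 (list median 1.03, adjusted p = 0.124, or 0.0201 without starved mRNA replicate 1). Histidine genes had 4 of 6 higher, with HIS4 at 1.30 and HIS5 at 1.14, and HIS6 lower at -1.31 (median 0.63, adjusted p = 0.235). Of 10 branched-chain genes 4 rose, led by LEU1, isopropylmalate isomerase, at 2.97 (SE 0.22), and 2 fell, LEU9 at -0.89 and ILV1 at -0.53 (median 0.30, adjusted p = 0.108, or 0.0229 without rich mRNA replicate 2). Lysine genes had LYS1 at 1.66 and LYS9 at 1.06 higher and LYS4 at -0.96 lower out of 7 (median 0.33, adjusted p = 0.407). Of 14 aromatic genes 5 rose, TRP5 at 1.03 most, and 3 fell, ARO9 at -4.10 and ARO7 at -1.31 among them. The median of 0.23 and the mean of -0.23 had opposite signs (adjusted p = 0.73, with the sign of the mean). When adjusted over the list alone the counts were the same in these lists, except for 5 lower in the aromatic list. The aspartate, threonine, serine, glycine and asparagine group had 7 of 15 higher (9 adjusted over the list alone) and 3 lower, with SER3, the first enzyme of serine synthesis, at 3.29 (SE 0.20), SER33 at 2.72, AAT1 at -1.68, GLY1 at -1.37 and SHM1 at -0.55. Its median was 0.51 and its camera adjusted p = 0.00981, or adjusted p = 0.629 with an estimated correlation. The call was lost with counts rebuilt from the alignments (adjusted p = 0.0819). GDH1, the glutamate dehydrogenase that fixes ammonia, was higher at 2.44 and PRO1 lower at -1.89 in the glutamate, glutamine and proline list. There 3 of 6 rose and 2 fell, with and without adjustment over the list alone (median 0.05, adjusted p = 0.805). Purine genes had 8 of 13 higher (9 adjusted over the list alone), ADE3 at 1.83 and ADE1 at 1.67, and IMD4 at -2.43 and GUA1 at -1.61 lower (median 0.90, adjusted p = 0.0509). The purine list passed when any library but the first of each mRNA group was left out and in 5 other alternatives (adjusted p between 0.00731 and 0.0416), and the branched-chain list also with DESeq2 (adjusted p = 0.0455).

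Stress and proteasome genes rose together, and nutrient genes were mixed. All 38 genes of the induced environmental stress response rose (38 adjusted over the list alone). Their median was 1.94 (1.80 within replicate 1 and 2.37 within replicate 2; camera adjusted p = 1.46e-30, adjusted p = 0.25 with an estimated correlation). Beside HSP12 and HXK1 they included SSA4, a cytosolic Hsp70, at 4.03 (SE 0.21) and PGM2, phosphoglucomutase, at 3.33 (SE 0.20). Of 32 proteasome subunits 30 rose, RPT1 at 1.47 and RPN6 at 1.42 among them, and RPN13 and PRE8 were not called. The median was 0.88, with 30 adjusted over the list alone (adjusted p = 1.8e-08, adjusted p = 0.25 with an estimated correlation). The list of autophagy and vacuolar proteases had 16 of 22 higher, with the vacuolar peptidases APE1 at 2.67, PEP4 at 2.43 and PRB1 at 2.41. ATG10 at -1.87 and ATG5 at -0.43 were lower, and the counts adjusted over the list alone were the same (median 0.98, adjusted p = 0.000182, adjusted p = 0.25 with an estimated correlation). Targets of nitrogen catabolite repression, the genes kept silent on good nitrogen sources, had 8 of 20 higher and 2 lower (MEP3 at -1.07 and OPT2 at -1.12), also when adjusted over the list alone. The general amino acid permease GAP1 rose by 4.21 (SE 0.23), the ammonium permease MEP2 by 2.86 and the GATA factor GAT1 by 2.36 (median 0.42, adjusted p = 0.011, adjusted p = 0.629 with an estimated correlation). Amino acid permeases went both ways, 8 of 17 higher and 5 lower (6 adjusted over the list alone), with SAM3 at 2.87 and AGP1 at 2.41 against TAT1 at -2.57 (median 0.28, adjusted p = 0.0783). Without rich mRNA replicate 2 or starved mRNA replicate 1 the permease list passed (adjusted p = 0.0433 and 0.00716), as with DESeq2 (adjusted p = 0.0455).

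Energy metabolism rose and phosphate genes fell. Of 33 nuclear-encoded respiratory genes 22 rose (22 adjusted over the list alone), including the succinate dehydrogenase subunits SDH4 at 1.67 and SDH1 at 1.65 (median 0.62, adjusted p = 0.000861, adjusted p = 0.629 with an estimated correlation). In glycolysis and fermentation 9 of 11 genes rose (11 adjusted over the list alone), PGK1 at 1.15 and ADH1 at 0.86, with PFK1 and PDC1 not called over all genes (median 0.60, adjusted p = 0.0126, adjusted p = 0.639 with an estimated correlation). The list call was lost without rich mRNA replicate 1 (adjusted p = 0.0568). Of 12 phosphate starvation genes 10 fell (11 adjusted over the list alone), with the regulator SPL2 at -2.66 and the phosphate transporter PHO84 at -2.14 (median -1.03, adjusted p = 0.000191, adjusted p = 0.505 with an estimated correlation). The remaining lists were not called. Mitochondrial ribosomal proteins had 4 of 68 higher, MRP8 at 1.42 most, and 8 lower (2 and 3 adjusted over the list alone; median -0.12; adjusted p = 0.73). Ergosterol genes had 6 of 24 higher and 7 lower (7 and 7; median 0.01; adjusted p = 0.976), with ERG9 at 0.91 and CYB5 at -1.10, and the iron regulon had 7 of 18 higher and 5 lower (7 and 6; median 0.01; adjusted p = 0.871), with ISU2 at 1.38. Histones had HHO1 at 1.20 higher and HTB1 at -0.99 and HTB2 at -0.87 lower of 4, the same when adjusted over the list alone (median -0.34, adjusted p = 0.805). Of 14 genes with characterised upstream open reading frames 5 fell, HEM3 at -1.45 most, and CAD1 at 0.83 and YAP1 at 0.57 rose, the same counts as adjusted over the list alone (median -0.32, adjusted p = 0.204). CAD1 was not called without starved mRNA replicate 2 (0.64, adjusted p = 0.0753). Sporulation genes had 6 of 12 lower (7 adjusted over the list alone), SPS4 at -3.67 and IME2 at -1.69, with a list median of -0.88 (adjusted p = 0.129). DMC1 was higher at 1.72, a call lost without replicate 2 of either mRNA group (0.65 and 1.03, adjusted p = 0.422 and 0.377). Of 7 MATa-specific genes, which mark the mating type of the strain, AGA2 rose by 0.63 and MFA2 and STE2 fell by 0.49 and 0.44, and none was called when adjusted over the list alone. The median was -0.04, or 0.05 under library totals, with adjusted p = 0.986. Each of these 3 calls was lost without replicate 2 of either mRNA group, and AGA2 also without replicate 1 (adjusted p between 0.0556 and 0.514). Of the 2 tested genes of the other mating type, SAG1 fell by 1.02 (adjusted p = 0.0356), which was lost without rich mRNA replicate 2 (-0.47, adjusted p = 0.542) and without replicate 1 or 2 of the starved mRNA (adjusted p = 0.062 and 0.158). STE3 was at -0.81 (adjusted p = 0.127).

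In all, 2574 of 5073 genes (50.7%) changed at the mRNA level, 1299 up and 1275 down, 549 and 683 of them by at least 2-fold. Of these, 2562 moved in the same direction within both replicate numbers. The 13 called lists all kept their sign within both numbers. Under library totals alone, without TMM factors, the median gene shifted to 0.09 and 57.3% of calls were increases in place of 50.5%.

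The second comparison was of ribosome footprints, starved over rich, which combine the change in mRNA with the change in its translation. Footprints on genes for making ribosomes fell. Ribosome biogenesis factors had all 113 members lower (113 adjusted over the list alone), with a median of -3.18 (-3.11 within replicate 1 and -3.23 within replicate 2). NSR1 fell by 5.17 on the log2 scale (SE 0.33, adjusted p = 2.4e-10), RRP5 fell by 4.78 (SE 0.26), ERB1 fell by 4.62 (SE 0.29), LTV1 fell by 4.52, KRE33 fell by 4.51 and HCA4 fell by 4.45. All 58 cytosolic ribosomal proteins (median -1.75, -1.60 and -1.93 within the replicate numbers) and all 20 polymerase subunits (median -2.13) fell as well, over all genes and adjusted over the list alone, RPL33B at -2.27, RPS22A at -2.20, RPA135 at -4.04 and RPA43 at -4.55 among them. For the 3 lists, camera gave adjusted p values of 8.06e-73, 1.27e-38 and 5.54e-16, and an adjusted p = 0.22, 0.163 and 0.236 with an estimated correlation.

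Stress and sulfur genes gained the most footprints. SUL1 rose by 7.51 (SE 0.36, adjusted p = 4.3e-12), SEO1 by 7.04 (SE 0.37) and GTO1, an omega-class glutathione transferase, by 7.01 (SE 0.61). HSP12 rose by 6.87 (SE 0.27), SER3 by 6.57 (SE 0.24, adjusted p = 1.91e-13) and SNZ1, of vitamin B6 synthesis, by 6.27 (SE 0.38). YIR016W had no footprint in either rich library and 6 and 22 in the starved ones, at least 11.6-fold higher, and NIT1 had none against 7 and 10, at least 7.07-fold higher. Of the 38 stress response genes 37 rose (37 adjusted over the list alone), PGM2 at 5.85 and SSA4 at 5.18 among them, and HSP78 at 0.04 was the exception. Their median was 3.52 (3.25 and 3.59 within the replicate numbers; camera adjusted p = 1.44e-53, adjusted p = 0.137 with an estimated correlation). The sulfur list had the same 24 of 25 higher (24 adjusted over the list alone), MET3 at 6.08, SUL2 at 6.11 and MET16 at 5.19, with a median of 3.93 and MET7 at -0.36 (adjusted p = 1.38e-41, adjusted p = 0.137 with an estimated correlation). Targets of nitrogen catabolite repression had 13 of 20 higher and none lower (14 adjusted over the list alone), GAP1 at 5.07, MEP2 at 4.21 and GAT1 at 2.66. The median was 2.24, or 1.98 with the 1 member that had no rich footprint set at its bound (adjusted p = 1.54e-06, adjusted p = 0.269 with an estimated correlation).

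Most translation factors lost footprints. Of 24 initiation factors 22 fell (23 adjusted over the list alone), TIF4631 at -2.35, the poly-A binding protein PAB1 at -2.27 and RPG1, an eIF3 subunit, at -2.13, while TIF4632 and HCR1 were not called (median -1.39, adjusted p = 2.5e-11, adjusted p = 0.216 with an estimated correlation). Elongation and termination factors had 7 of 8 lower with or without adjustment over the list alone, YEF3 at -2.42 and RLI1 at -2.29, and CAM1 at -0.20 not called (median -1.50, adjusted p = 3.91e-05, adjusted p = 0.357 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases 16 fell by both counts, GLN4 at -1.73 and MES1 at -1.68, with GUS1 and DPS1 not called (median -0.97, adjusted p = 6.61e-06, adjusted p = 0.425 with an estimated correlation). Here and further on, both counts are those over all genes and adjusted over the list alone. Of 13 regulators of general amino acid control 11 fell (12 adjusted over the list alone), GCD2 at -1.76 and GCD11 at -1.74, both in eIF2 or its exchange factor. GCN4, the transcription factor that the pathway controls, rose by 2.03 (SE 0.23, adjusted p = 4.81e-07). The list's median was -1.06 (adjusted p = 0.0056, adjusted p = 0.395 with an estimated correlation). GCN2, the kinase that senses uncharged tRNA, fell by 0.78 (adjusted p = 0.00286), a call lost without starved footprint replicate 2 (-0.58, adjusted p = 0.113) and under library totals (-0.34, adjusted p = 0.151).

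Of the biosynthetic lists, arginine, purine and the permeases passed. Arginine genes had 4 of 8 higher (5 adjusted over the list alone), ARG1 at 2.50 and ARG4 at 1.41 among them (median 0.98, adjusted p = 0.0323, adjusted p = 0.511 with an estimated correlation). Purine genes had 10 of 13 higher and IMD4 and GUA1 lower, the same adjusted over the list alone, with ADE17 at 2.76 and ADE2 at 2.39 (median 1.26, adjusted p = 0.00169, adjusted p = 0.511 with an estimated correlation). Permeases had 9 of 17 higher and 5 lower by both counts, AGP1 at 3.09 against TAT1 at -2.84 (median 0.73, adjusted p = 0.0137, adjusted p = 0.517 with an estimated correlation). Histidine genes had 4 of 6 higher, HIS5 at 2.00, and HIS6 at -1.10 lower, by both counts (median 0.83, adjusted p = 0.0821). This list passed under library totals, with DESeq2 and without replicate 2 of either footprint group (adjusted p between 0.023 and 0.0452). The aspartate and serine group had 6 of 15 higher, SER33 at 3.55 and SHM2 at 2.34 behind SER3, and 4 lower, GLY1 at -2.65 most, by both counts (median 0.30, adjusted p = 0.057). It passed in the same 4 settings (adjusted p between 0.0013 and 0.0334). Branched-chain genes had LEU1 at 1.57, BAT1 and LEU4 higher and 5 of 10 lower by both counts, with a median of -0.41 that was 0.00 under library totals (adjusted p = 0.96). Lysine genes had LYS1 at 1.27 higher and LYS4 at -2.03 lower of 7, also adjusted over the list alone, with a median of -0.08, or 0.34 under library totals (adjusted p = 0.96). Aromatic genes had TRP1 at 0.88 higher and 5 of 14 lower (7 adjusted over the list alone), ARO9 at -1.77 most, with a median of -0.27, or 0.14 under library totals (adjusted p = 0.427). TRP1 was not called without rich footprint replicate 1 (0.64, adjusted p = 0.0536). The glutamate group had GDH1 at 1.33 and GLN1, glutamine synthetase, at 1.29 higher and PRO1 at -2.13 and GLT1 at -1.02 lower of 6 by both counts, with a median of -0.11, or 0.30 under library totals (adjusted p = 0.96).

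As lists, proteasome, autophagy and respiration rose and phosphate fell. Proteasome subunits had 12 of 32 higher (11 adjusted over the list alone), PRE3 at 0.79 and RPN8 at 0.70 (median 0.34, adjusted p = 0.0154, adjusted p = 0.303 with an estimated correlation). Autophagy and vacuolar proteases had 15 of 22 higher (18 adjusted over the list alone), APE1 at 3.02 and ATG19 at 2.30 (median 1.34, adjusted p = 6.61e-06, adjusted p = 0.216 with an estimated correlation). Respiratory genes had 27 of 33 higher (29 adjusted over the list alone), SDH2 at 1.65 and CYT1 at 1.33, and CYC1, cytochrome c, lower at -0.49 (median 0.67, adjusted p = 3.97e-05, adjusted p = 0.424 with an estimated correlation). CYC1 was not called without any 1 of 6 libraries (-0.32 to -0.65, adjusted p between 0.0695 and 0.274) or under library totals (-0.06). Phosphate starvation genes had 9 of 12 lower (10 adjusted over the list alone), PHO84 at -2.87 and VTC3 at -1.87 (median -1.22, adjusted p = 0.000654, adjusted p = 0.425 with an estimated correlation). Glycolysis and fermentation had PDC1 at -0.81, CDC19 at -0.58 and HXK2 at -0.54 lower of 11 (2 adjusted over the list alone), with a median of -0.20 that was 0.21 under library totals (adjusted p = 0.545). PDC1, CDC19 and HXK2 were lost without starved footprint replicate 2 (-0.59, -0.28 and -0.47, adjusted p = 0.0502, 0.348 and 0.123). CDC19 was also lost without any 1 rich footprint or starved mRNA library, HXK2 without rich footprint replicate 2 or starved footprint replicate 1 (-0.31 to -0.58, adjusted p between 0.0576 and 0.261), and both under library totals (-0.18 and -0.13), among other settings.

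No other list was called in footprints. Mitochondrial ribosomal proteins had 4 of 68 higher (1 adjusted over the list alone), MRP8 at 1.40 (median 0.15, adjusted p = 0.322). Ergosterol genes had 11 of 24 lower, ERG3 at -1.80, and 2 higher, ERG28 at 0.71 and ERG9 at 0.46, the same adjusted over the list alone. ERG28 was lost without rich footprint replicate 2 (0.51, adjusted p = 0.132). The list's median was -0.33, or 0.08 under library totals (adjusted p = 0.0986), and it passed without starved footprint replicate 1 (adjusted p = 0.0271). The iron regulon had HMX1, heme oxygenase, at 2.30, ISU2 and ENB1 higher and FRE1 at -3.64 and FIT1 lower of 18 by both counts (median 0.16, adjusted p = 0.857). HMX1 was lost without replicate 2 of either footprint group (1.78 and 1.68, adjusted p = 0.0533 and 0.166). Histones had HTB2 at -0.99 and HTB1 at -0.69 lower of 4 by both counts, with a median of -0.40, or 0.02 under library totals (adjusted p = 0.545). HTB1 was lost without rich footprint replicate 2 (-0.52, adjusted p = 0.0578). Genes with characterised upstream open reading frames had GCN4, SCO1 and CLN3 higher and 5 of 14 lower by both counts, with a median of -0.21, or 0.23 under library totals (adjusted p = 0.833). Of the MATa-specific genes MFA2 fell by 0.68, also adjusted over the list alone, with a list median of -0.03, or 0.39 under library totals (adjusted p = 0.96). The MFA2 call was lost without starved footprint replicate 2 or replicate 1 of the rich ones (-0.38 and -0.52, adjusted p = 0.212 and 0.0775). Sporulation genes had ZIP1 at 1.09 higher of 12 and none adjusted over the list alone, with a median of 0.80, or 0.73 with the members lacking rich footprints at their bound or left out (adjusted p = 0.557). ZIP1 was lost without replicate 2 of either footprint group (0.77 and 0.59, adjusted p = 0.193 and 0.477). SAG1 and STE3 of the other mating type were at -0.12 and 0.11 (adjusted p = 0.93 for both).

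Footprints changed on 2220 of 5073 genes (43.8%), 1062 up and 1158 down, 620 and 706 of them by at least 2-fold. Of these, 2204 moved in the same direction within both replicate numbers, and all 17 called lists kept their sign there. Without starved footprint replicate 2 1477 genes were called. Under library totals the median gene shifted by 0.46 and 74.3% of calls were increases in place of 47.8%, so increases and decreases are relative to the mean gene.

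Across genes the mRNA and footprint changes, which share no library, were correlated (Pearson's r = 0.733 and Spearman's rho = 0.679 over 5073 genes, which are not independent replicates). A gene was called higher in both for 755 genes, where independent calls would give 271.9, and lower in both for 778, where they would give 291. Opposite calls were rarer: 27 genes had higher mRNA and lower footprints, against 296.5, and 19 had the reverse, against 266.9.

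Translational efficiency within each condition came next. Of the 6 highest in rich medium, among genes with at least 100 reads in both rich mRNA libraries, pyruvate decarboxylase PDC1 stood at a log2 ratio of 4.57 (SE 0.24), PAB1 at 4.16 (SE 0.21), SCP160 at 4.11 (SE 0.19), the co-chaperone STI1 at 4.10 (SE 0.20), the mitochondrial Hsp70 SSC1 at 4.07 (SE 0.20) and the RNA helicase DED1 at 4.04 (SE 0.20). The lowest were YJL213W at -7.65 (SE 0.75) and ISC10, a gene of sporulation, at -7.13 (SE 0.62), both with 1 footprint, then YCR024C-B at -6.21, YER186C at -6.02, DAL7 at -5.23 (SE 0.29) and STN1 at -4.84. All 12 passed with adjusted p of 3.94e-08 or less. Efficiency differed from the mean gene for 3463 genes in rich medium (1768 higher, 1695 lower) and for 2840 in starved cells (1455 higher, 1385 lower). Under library totals alone 13.3% of the calls in rich medium were higher in place of 51.1%, the median gene shifted by -1.17 and 375 calls changed sign, and in starved cells 15.4% were higher with a median of -0.91. Among genes with at least 100 mRNA reads over the replicates, the SD of log2 efficiency was 1.41 in rich medium (4538 genes) and 1.05 in starved cells (4261), and from the 5th to the 95th percentile efficiencies spanned 21.4-fold and 10.1-fold. Within the replicate numbers the SDs were 1.37 and 1.35 in rich medium and 1.16 and 0.99 in starved cells.

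Last came the change in translational efficiency relative to the mean gene. SER3 gained 3.29 on the log2 scale (SE 0.28, adjusted p = 1.96e-06). GTO1 gained 5.30 (SE 0.79, adjusted p = 0.000531), GCY1, a glycerol dehydrogenase, 3.62 (SE 0.46) and CTT1, cytosolic catalase, 3.56 (SE 0.49). Next came YCT1 at 3.45 (SE 0.63) and DUR3 at 3.33 (SE 0.53). The largest decreases were JIP5 at -2.86 (SE 0.37, adjusted p = 0.00023) and NSR1 at -2.85 (SE 0.42, adjusted p = 0.000531), followed by ERB1 at -2.31, SPB1 at -2.30, NOP14 and NOP2 at -2.29, KRI1 at -2.25 and ENP1 at -2.19, all of ribosome assembly. ERB1, SPB1, NOP14 and ENP1 were not called without starved footprint replicate 2 (-1.86, -2.22, -2.27 and -2.19, adjusted p between 0.0698 and 0.0794). YIR016W and NIT1, with no footprint in rich medium, were also among the 8 largest increases, and NIT1 was not called without rich footprint replicate 2 (adjusted p = 0.0743). ISC10 stood at 4.36 (SE 1.33, adjusted p = 0.0387), but at -1.27 without starved footprint replicate 2. It was not called without either rich footprint library or rich mRNA replicate 1. Of 225 genes with higher efficiency, 223 exceeded what the largest admixture of mRNA fragments would give, 170 by at least 2-fold. NIT1 did not (log2 excess -0.19). Decreases were not checked, and admixture could add to them, as it lowered the rich SD from 1.357 to 1.077.

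Genes for the translation machinery lost efficiency as lists. Ribosome biogenesis factors had 49 of 113 lower and none higher (75 adjusted over the list alone), NSR1, RRP5 at -2.06 and NOP2 among them, with a median of -1.09 (-1.35 within replicate 1 and -0.79 within replicate 2; adjusted p = 1.38e-22, adjusted p = 0.444 with an estimated correlation). Cytosolic ribosomal proteins had 10 of 58 lower by both counts, with a median of -0.39 (-0.36 and -0.46 within the replicate numbers; adjusted p = 1.4e-06, adjusted p = 0.444 with an estimated correlation). RPL17A, at -1.10, was not called without starved footprint replicate 2 (-0.88, adjusted p = 0.072). Polymerase subunits had 6 of 20 lower (7 adjusted over the list alone), RPA43 at -1.90 and RPA49 at -1.43, with a median of -0.61 (adjusted p = 0.00406, adjusted p = 0.541 with an estimated correlation). That call was lost without starved mRNA replicate 1 (adjusted p = 0.0526), and RPA43 and RPA49 were not called without rich footprint replicate 2 (-1.65 and -1.31, adjusted p = 0.0607 and 0.0567), nor RPA43 without replicate 2 of the starved ones (-1.69, adjusted p = 0.16). Of 24 initiation factors 9 were lower (18 adjusted over the list alone), PAB1 at -1.98 (SE 0.27, adjusted p = 0.00031) and RPG1 at -1.29, with a median of -0.72 (adjusted p = 5.46e-09, adjusted p = 0.389 with an estimated correlation). Of 18 aminoacyl-tRNA synthetases 8 were lower (12 adjusted over the list alone), FRS2 at -1.45 (SE 0.23) and GUS1 at -1.17, with a median of -0.67 (adjusted p = 3.18e-07, adjusted p = 0.394 with an estimated correlation). All 8 elongation and termination factors were lower when adjusted over the list alone and 5 over all genes, CAM1 at -1.16 most, with a median of -0.83 (adjusted p = 7.23e-05, adjusted p = 0.394 with an estimated correlation). CAM1 was not called without starved footprint replicate 2 (-0.90, adjusted p = 0.0675). The regulators of general amino acid control had GCN4 higher and GCD11, GCD2, GCN20 and GCN1 lower of 13 (1 and 9 adjusted over the list alone), with a median of -0.72 (adjusted p = 0.014, adjusted p = 0.394 with an estimated correlation). Without starved footprint replicate 2 the list call was lost (adjusted p = 0.0532), and so were GCD11, GCD2 and GCN20 (-0.67, -0.93 and -0.93, adjusted p = 0.184, 0.193 and 0.0679).

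Stress and nitrogen lists gained efficiency. Of 38 stress response genes 15 were higher and none lower (17 adjusted over the list alone), with a median of 0.67 (0.99 and 0.64 within the replicate numbers; adjusted p = 1.91e-14, adjusted p = 0.389 with an estimated correlation). RTN2 stood at 5.14 (SE 0.61), PGM2 at 2.52 (SE 0.29, adjusted p = 8.43e-05) and MSC1 at 2.38 (SE 0.35). Targets of nitrogen catabolite repression had 8 of 20 higher (12 adjusted over the list alone), GLN1 at 1.59 (SE 0.25) and DUR3 among them, and CPS1 lower at -1.23. The median of 1.42 did not move with the bounded member at its bound (adjusted p = 3.56e-07, adjusted p = 0.389 with an estimated correlation). DAL7 at 2.63 and CPS1 were not called without starved footprint replicate 2 (2.40 and -0.91, adjusted p = 0.0517 and 0.102), nor CPS1 without replicate 1 of the rich ones (-0.98, adjusted p = 0.064). Mitochondrial ribosomal proteins had RSM28 alone called of 68, and none when adjusted over the list alone, yet as a list they were higher, with a median of 0.25 (adjusted p = 0.00488, adjusted p = 0.389 with an estimated correlation). RSM28 stood at 0.82 (adjusted p = 0.0437) and was not called without any 1 of 6 libraries (0.73 to 1.04, adjusted p between 0.0697 and 0.195). Sporulation genes had ZIP1, SPS4 and IME2 higher of 12 (3 adjusted over the list alone), with a median of 1.41, or 1.34 with bounded members at their bound (adjusted p = 0.0134, adjusted p = 0.389 with an estimated correlation). That list was not called without starved footprint replicate 2 (adjusted p = 0.314) or under library totals (adjusted p = 0.136). None of its 3 genes was called without that library, which turned SPS4 from 3.32 to -2.29 (adjusted p = 0.806).

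Metabolic lists with lower efficiency were glycolysis, the proteasome, ergosterol and branched-chain synthesis. Glycolysis and fermentation had 5 of 11 lower (11 adjusted over the list alone), with a median of -0.80 (adjusted p = 1.19e-07, adjusted p = 0.394 with an estimated correlation). The pyruvate kinase CDC19, at -1.35 (SE 0.31, adjusted p = 0.00899), was not called without starved footprint replicate 2 (-1.04, adjusted p = 0.0517). Proteasome subunits had 9 of 32 lower (12 adjusted over the list alone), RPN6 at -1.13 and RPN1 at -1.09, with a median of -0.47 (adjusted p = 1.02e-05, adjusted p = 0.389 with an estimated correlation). Of 24 ergosterol genes ERG6, at -1.13 (SE 0.23), ERG3, MVD1 and ERG1 were lower (5 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00489, adjusted p = 0.556 with an estimated correlation). Without starved footprint replicate 2 this list call was lost (adjusted p = 0.149), and so were ERG3, MVD1 and ERG1 (-0.94, -0.88 and -0.89, adjusted p = 0.109, 0.0959 and 0.118). Of 10 branched-chain genes ILV6 at -1.47, LEU1 at -1.40 and ILV3 were lower (4 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00459, adjusted p = 0.541 with an estimated correlation). Without starved mRNA replicate 2 the list and ILV3 (-0.84) were not called (adjusted p = 0.0702 and 0.0515). Purine genes had MTD1 at 1.80 (SE 0.25) and ADE17 at 1.34 higher of 13 (4 adjusted over the list alone), with a median of 0.12 (adjusted p = 0.0449, adjusted p = 0.663 with an estimated correlation). The purine call was lost without replicate 1 of either footprint group or replicate 2 of either mRNA group (adjusted p between 0.182 and 0.336) and with a replicate block (adjusted p = 0.0505), and its median was 0.36 within replicate 1 and 0.00 within replicate 2. ADE17 was not called without rich mRNA replicate 2 (1.09, adjusted p = 0.0503). Under library totals the medians of the lists called lower were between -0.74 and -0.06, the latter for ribosomal proteins, with -0.26 for polymerase subunits, -0.15 for the proteasome and -0.12 for ergosterol.

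The sulfur list showed no common change of efficiency. In it SUL2, a sulfate permease, at 2.00 (SE 0.39), MET13 and MET16 were higher and CYS3, cystathionine gamma-lyase, at -1.33 (SE 0.25), SAM2, SAM1 and MMP1 lower of 25 (4 and 4 adjusted over the list alone). The median was -0.13, or 0.22 under library totals (adjusted p = 0.959). MET13, at 1.66, was lost without rich footprint replicate 2 or rich mRNA replicate 2 (1.5 and 1.29, adjusted p = 0.0569 and 0.125), and SAM2, at -1.02, without starved footprint replicate 2 (-0.86, adjusted p = 0.0659). In the aspartate and serine group SER3, SER33 and SHM2 were higher and AAT2, GLY1, THR1 and HOM6 lower of 15 (3 and 8 adjusted over the list alone; median -0.62; adjusted p = 0.827). AAT2, GLY1 and THR1 were lost without starved footprint replicate 2 (-0.80, -0.78 and -0.71, adjusted p = 0.121, 0.192 and 0.17). GLN1 was higher and GDH1, at -1.11 (SE 0.24), and PRO2 lower among 6 of the glutamate group, the same adjusted over the list alone (median -0.39, adjusted p = 0.5). PRO2, at -0.72, was lost without any 1 of the 8 libraries (-0.60 to -0.76, adjusted p between 0.0588 and 0.146). Arginine genes had ARG8 higher of 8 at 1.64 (2 higher and 1 lower adjusted over the list alone; median 0.04; adjusted p = 0.472). ARG8 was lost without starved footprint replicate 2 (1.80, adjusted p = 0.0753). Aromatic genes had ARO9 at 2.33 higher and TRP2 and TRP5 lower of 14 (1 and 4 adjusted over the list alone), with a median of -0.27, or 0.07 under library totals (adjusted p = 0.564). Without starved footprint replicate 2 none of these 3 was called (1.86, -0.69 and -0.57, adjusted p = 0.056, 0.175 and 0.215). HIS5 at 0.86 was higher among 6 histidine genes (1 adjusted over the list alone; median 0.12; adjusted p = 0.272) and LYS4 at -1.07 lower among 7 lysine genes (2 adjusted over the list alone; median -0.39; adjusted p = 0.233). Neither was called without starved footprint replicate 2 (0.89 and -0.76, adjusted p = 0.0807 and 0.282). The lysine list passed without starved footprint replicate 1 (adjusted p = 0.0485). Permeases had AGP3 at 3.96 and DIP5 at 1.34 higher of 17 (2 adjusted over the list alone; median 0.06; adjusted p = 0.193). Both were lost without replicate 2 of either footprint group (2.74 and 1.44, then 4.25 and 0.98, adjusted p between 0.0517 and 0.131). The permease list passed without rich mRNA replicate 1 or starved mRNA replicate 2 (adjusted p = 0.0411 and 0.0254). In autophagy ATG19 at 2.21 (SE 0.32) was higher and CPS1 lower of 22 (2 and 1 adjusted over the list alone; median 0.14; adjusted p = 0.193), and no respiratory gene of 33 was called by either count (median 0.03, adjusted p = 0.358). Phosphate genes had VTC4 lower of 12 at -0.80 (1 higher and 1 lower adjusted over the list alone), with a median of -0.01, or 0.33 under library totals (adjusted p = 0.959). Histones had HHO1 lower of 4 at -0.83 by both counts, with a median of -0.22, or 0.12 under library totals (adjusted p = 0.564), while the iron regulon had FET3 lower of 18 at -1.24 by both counts (median 0.20, adjusted p = 0.959). VTC4 and HHO1 were not called without rich footprint replicate 2 or rich mRNA replicate 1 (-0.52 to -0.76, adjusted p between 0.131 and 0.251), nor VTC4 without starved footprint replicate 1 (adjusted p = 0.141), and FET3 not without rich footprint replicate 1 (-0.86, adjusted p = 0.064). No MATa-specific gene of 7 was called by either count (median -0.19, or 0.13 under library totals, adjusted p = 0.959), and SAG1 and STE3 were at 0.90 and 0.92 (adjusted p = 0.582 and 0.549). Genes with characterised upstream open reading frames had GCN4 higher and TIF4631 lower of 14 (2 and 1 adjusted over the list alone; median 0.18; adjusted p = 0.272). TIF4631, at -1.18, was lost without starved footprint replicate 2 (-0.87, adjusted p = 0.0888).

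**Figure D2:**
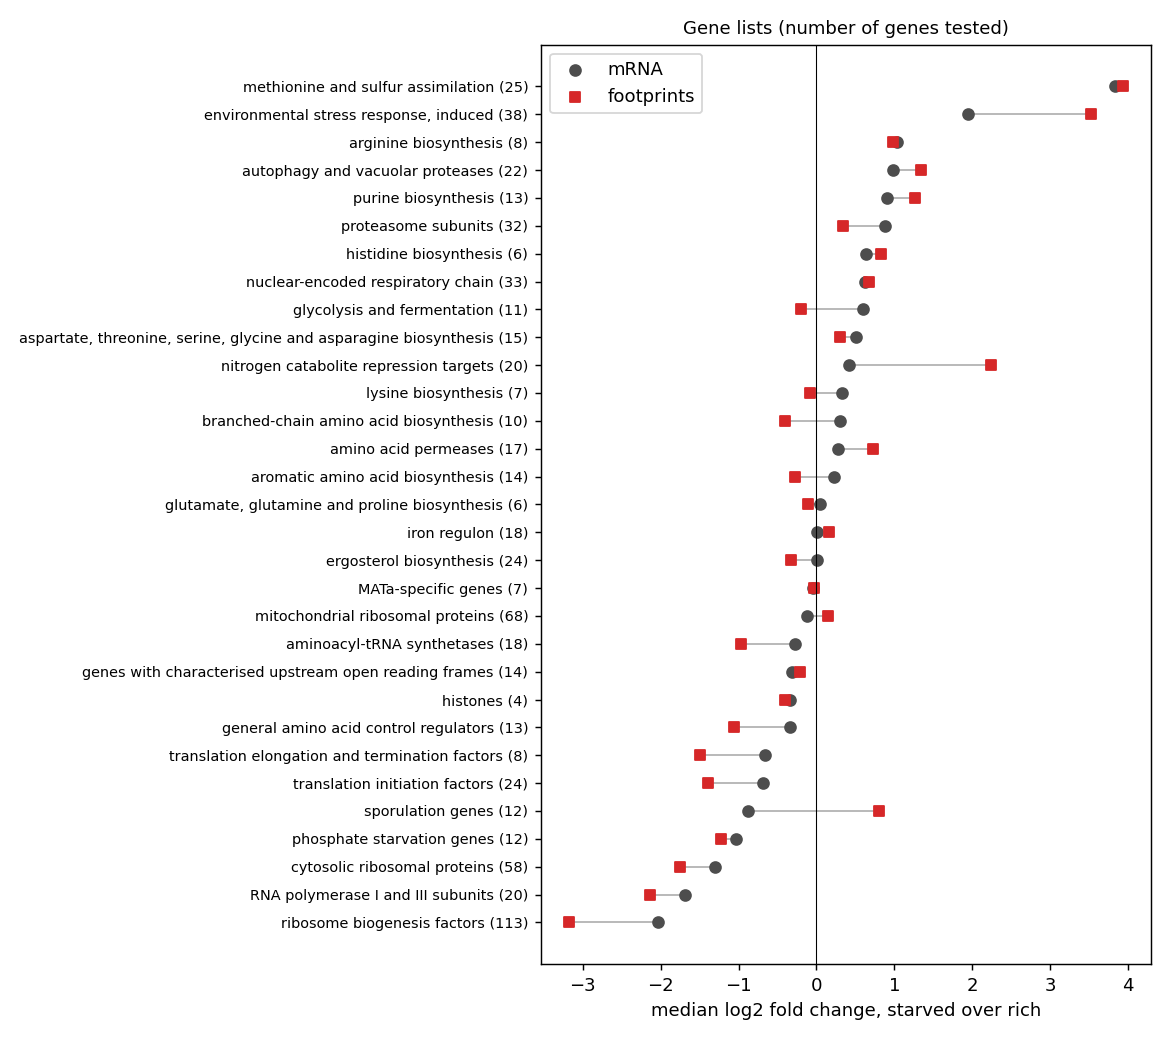
Median log2 fold change, starved over rich, of the tested members of each gene list (horizontal axis), with dots for mRNA and squares for footprints under TMM scaling. Ribosome biogenesis factors lie at -2.03 and -3.18 and the sulfur list at 3.83 and 3.93; under library totals the footprint medians of lysine, branched-chain and aromatic synthesis, the glutamate group, glycolysis, ergosterol, histones, genes with upstream frames and MATa-specific genes are 0.00 or higher, and so is the mRNA median of the MATa-specific genes.

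Efficiency changed for 607 of 5073 genes (12%), 225 up and 382 down, 208 and 234 of them by at least 2-fold, each in the same direction within both replicate numbers. Of the 225, 61 had more mRNA and more footprints, 76 more footprints with no mRNA call and 57 less mRNA with no footprint call. Of the 382, 120 had less of both, 107 more mRNA with no footprint call and 99 fewer footprints with no mRNA call. Single libraries decided much of this count: 372 and 226 genes were called without replicate 1 or 2 of the rich footprints, 131 without starved footprint replicate 2 and 338 without rich mRNA replicate 1. Under library totals alone 80.1% of 659 calls were increases in place of 37.1%, with the median gene at 0.29. Within both replicate numbers 15 of the 16 called lists kept their sign, the purine list being the exception.

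GCN4 encodes the transcription factor of general amino acid control, and short frames in its leader are known to control its translation. Its coding sequence lies on the minus strand of chromosome V from 138918 to 139763 (YEL009C, 846 nt) in the authors' build. Its mRNA stood at -0.24 (SE 0.19, adjusted p = 0.303), its footprints rose by 2.03 (SE 0.23, adjusted p = 4.81e-07) and its efficiency rose by 2.27 (SE 0.30, adjusted p = 0.00023). The deposited RPKM of its footprints was 38.5 ± 0.513 (SD, n = 2) in rich medium and 206 ± 84.4 in starved cells, against 595 ± 64.8 and 537 ± 31.5 for its mRNA. Counted from the alignments per 1000000 coding footprints, the coding sequence went from 56.1 ± 0.8 to 248.8 ± 92.0, a 4.44-fold rise, which was between 3.28-fold and 5.6-fold when any footprint library was left out. Its leader holds 4 short ATG frames in the rebuilt sequence: frame 1 from 140113 to 140124, frame 2 from 140048 to 140056, frame 3 from 139928 to 139939 and frame 4 from 139903 to 139914. Footprints on frame 4 went from 10.7 ± 3.6 to 2.3 ± 1.6 on the same scale and on frame 3 from 17.4 ± 8.6 to 3.2 ± 0.3. Frame 1 went from 120.3 ± 92.9 to 55.4 ± 15.2, a difference smaller than the spread between its rich replicates, and frame 2 from 7.7 ± 3.8 to 2.9 ± 0.7. Replicate 1 of the starved footprints had 2 reads in each of frames 2, 3 and 4. The stretch upstream of frame 1 went from 132.4 ± 32.3 to 224.5 ± 15.7. In a division made after the values were seen, its 15 nt next to frame 1 went from 110.9 ± 34.8 to 69.9 ± 4.2 and the rest from 21.5 ± 2.6 to 154.6 ± 11.5, a 7.18-fold rise, with mRNA in the rest at 114.2 ± 29.3 and 127.4 ± 48.

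**Figure D3:**
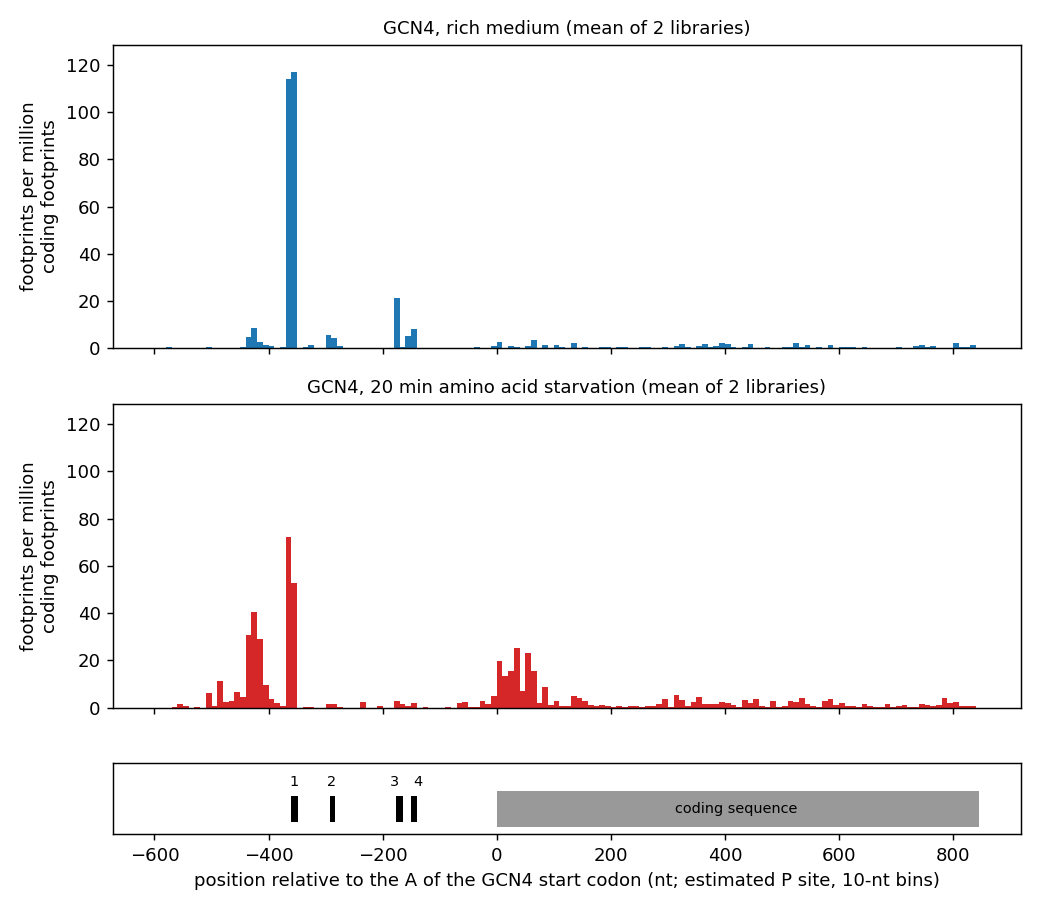
Footprints per 1000000 coding footprints in bins of 10 nt against the position from the GCN4 start codon, in rich medium (top) and after starvation (bottom), above a map of upstream frames 1 to 4 and the coding sequence. The coding sequence holds 56.1 in rich medium and 248.8 in starved cells.

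CPA1, on chromosome XV from 882897 to 884132 (plus strand, YOR303W), encodes the small subunit of the arginine-specific carbamoyl phosphate synthetase and carries an upstream frame. Its mRNA fell by 1.15 (SE 0.17, adjusted p = 1.52e-05), its footprints were at -0.32 (adjusted p = 0.285) and its efficiency at 0.83 (adjusted p = 0.0691), which passed under library totals (1.18, adjusted p = 0.0152). GCN2 was at -0.14 in mRNA (adjusted p = 0.504) and -0.64 in efficiency (adjusted p = 0.107).

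Footprints upstream of start codons took a larger share in starved cells. In the 150-nt leaders of 4473 genes they made up 2.40% and 2.61% of leader and coding footprints together in rich medium and 4.83% and 5.48% in starved cells, a 2.06-fold rise of the mean. The mRNA libraries had 6.42% and 4.50% in rich medium and 6.11% and 3.98% in starved cells. Of 2436 leaders tested, 415 rose and 13 fell by edgeR, with a median log2 change of 1.04 where the coding sequences of the same genes had -0.01, and 78.1% of leaders lay above their coding sequence. GPH1, glycogen phosphorylase, had no leader footprint in rich medium and 26 and 45 in starved cells, at least 29.5-fold higher. The leaders of TMA17, SUL2, GSY1, glycogen synthase, and YOR131C also had none in rich medium and were at least 21.2-fold, 17.9-fold, 11.6-fold and 10.4-fold higher. GSY1 and YOR131C were not called without starved footprint replicate 2. Leaders that fell were those of GPI18, AIM41 at -4.50 (adjusted p = 0.0206), CHA1 at -3.41 (adjusted p = 0.0255), VHR2 at -3.20 and COG2 at -3.19. Each was lost without either starved footprint library, and without rich footprint replicate 2 AIM41 stood at -0.14 and COG2 at -0.99. CHA1 was also lost without rich footprint replicate 1 (-2.48), and GPI18 and VHR2 without replicate 2. GCN4's leader was at 0.37 (adjusted p = 0.691), where the window cuts through frame 4, and at 3.31 (adjusted p = 0.0305) with a window of 100 nt that leaves that frame out. CPA1's was at -0.23 (adjusted p = 0.779).

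Counted in the 5' UTRs that the authors list, the share of footprints among all listed reads went from 0.498% and 0.611% in rich medium to 2.75% and 3.55% in starved cells, and 900 of 1370 UTRs rose and 6 fell, a count added after the data were seen. Leader footprints relative to leader mRNA had a median change of 1.28, but edgeR called none of the 2436, with 620 at an unadjusted p under 0.05, of which 606 were higher. Single libraries moved the number of called leaders: 157 without rich footprint replicate 2, 247 and 41 without replicate 1 or 2 of the starved footprints and 657 without starved mRNA replicate 1. Of simulated leaders changed by 4-fold, 7.6% were called, so there, with 200 changed, most changes of that size were missed.

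**Figure D4:**
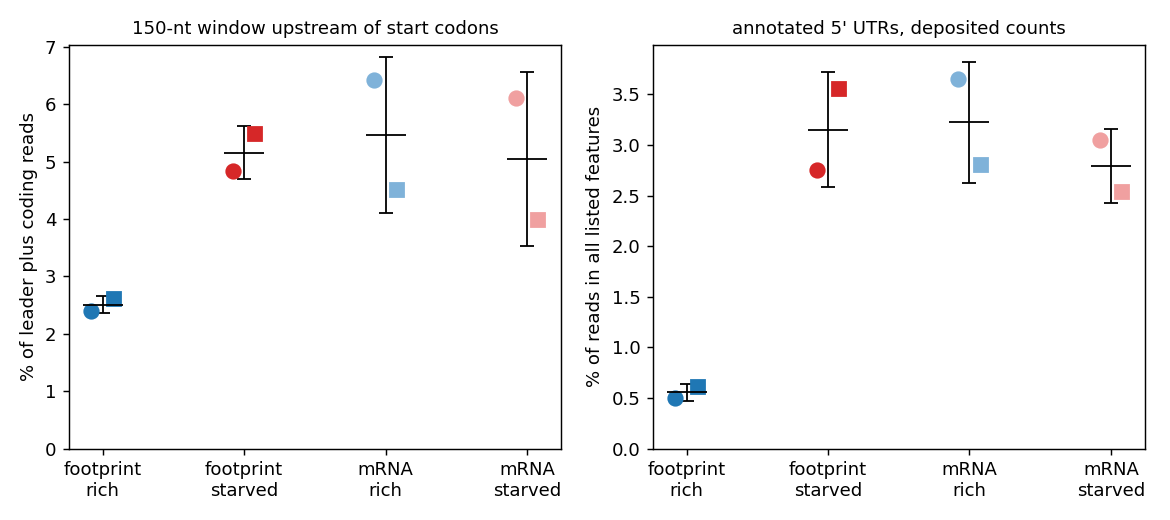
Percent of leader and coding reads that fall in the 150-nt window upstream of the start codon (left) and percent of all listed reads in the authors' 5' UTRs (right), for each group, with circles for replicate 1, squares for replicate 2 and a line with bars for the mean and SD. Footprint shares lie at 2.40% and 2.61% in rich medium and 4.83% and 5.48% in starved cells on the left, and mRNA shares show no such step.

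Genes deleted in the strain served as a check of the labels. MET17, the current name of MET15, had 1 read over the 8 libraries, in the mRNA from rich medium. HIS3 had reads in all 8, with a footprint RPKM of 128.1 and 320.1 in rich and starved cells and an mRNA RPKM of 101 and 267.2. Its mRNA rose by 1.29 (SE 0.19, adjusted p = 1.11e-05) and its footprints by 0.89 (SE 0.18, adjusted p = 0.00049), with its efficiency at -0.40 (adjusted p = 0.32). How much of HIS3 the deletion in the labels leaves in place was not examined. LEU2 and URA3 were not analysed here.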

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

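The tests of start-codon footprints, of mRNA fragments, of a few leaders and of cycloheximide as sources of the leader footprints were chosen after the result was seen, as were the counts in the deposited 5' UTRs.

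Some kinds of listed features outside the nuclear coding sequences held a larger percent of the listed reads in starved cells than in rich medium, both for footprints and for mRNA. In footprints, 5' UTRs rose from 0.554 ± 0.08 (SD, n = 2) to 3.15 ± 0.568, 3' UTRs from 0.164 ± 0.084 to 0.588 ± 0.335 and tRNAs from 0.042 ± 0.009 to 0.0765 ± 0.028. In mRNA, snRNAs and snoRNAs went from 0.734 ± 0.059 to 0.904 ± 0.074, other noncoding RNAs from 0.227 ± 0.016 to 0.344 ± 0.057 and mitochondrial coding sequences from 0.014 ± 0.004 to 0.0275 ± 0.005. These stood out because both starved libraries lay above both rich ones, which chance alone gives often with 2 libraries against 2 (exact p = 0.33).

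The leader footprints are the largest of these differences. Footprints on start codons that spill into the window were argued against: without the 15 nt next to the start codon the lowest starved share was 3.24% and the highest rich share 1.775%. Admixture of mRNA fragments was argued against: to raise the highest rich share to the lowest starved one it would need to be 63.3% of a starved library, where the 3' UTR reads allow at most 8.25%, if such fragments spread as in the mRNA libraries. A few leaders with many reads were argued against too, since without the 20 leaders with most footprints the lowest starved share was 3.99% and the highest rich share 1.874%. Cycloheximide, which may let ribosomes enter leaders after elongation stops, cannot be told apart from a change in the cells, as 0 libraries lacked it. The medium shift itself stays open.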

How the results depend on the processing

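Library sizes from the listed coding reads, the deposited 5' UTR counts, the window without the 15 nt next to the start codon, the omission of 20 leaders and the omission of single libraries for GCN4 were chosen after the data were seen. The other alternatives were set before.

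The number of called genes stayed within 1.5 times the reported number for mRNA in each alternative, between 1860 and 2593 without single libraries. For footprints it was between 1477 (without replicate 2 of the starved footprints) and 2285, and for the change of efficiency between 131 and 763. Efficiency calls fell by over 1.5 times without the libraries named in the results and with DESeq2 (361). Fewer libraries lower the power by construction, and for DESeq2 the cause was not tested. Where a group kept 1 library, that library was assumed to vary like the others.

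Of 2968 values of single genes without a library, 2724 kept their direction and side of the threshold, 242 lost a call and 2 reversed. Both reversals came without replicate 2 of the starved footprints: the efficiency of ISC10, at -1.27 there and at most 7.22 without others (there with no rich footprint left, so no bound), and of SPS4, at -2.29 and at most 4.1. With other settings 3582 of 3669 were the same, 85 lost a call and 2 gained one. Library totals alone ended 31 of 371 calls, and replicate 2 of the starved footprints ended 67.

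Of the gene lists, 13, 17 and 16 were called for mRNA, footprints and efficiency. With an estimated correlation 0, 0 and 0 passed, and 5, 6 and 3 at unadjusted p under 0.05. Fry, which asks whether a list moves as a whole and compares it with no other genes, called 22, 22 and 3. Without single libraries the numbers were 13 to 16, 17 to 19 and 13 to 17.

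Replicate numbers differ technically: reads with a single position and no mismatch were 51.5% to 57.8% of aligned reads in replicate 1 and 26.6% to 32.9% in replicate 2. Deviations from the group mean correlated across 2537 genes by 0.208 (footprints, rich and starved), 0.167 (mRNA, rich and starved), 0.038 and 0.073 (footprints and mRNA within rich or starved) and -0.155 and -0.124 (across both). The numbers were not treated as pairs. With a replicate block 2605 genes were called for mRNA, 2225 for footprints, 621 for efficiency, 477 for leaders and 13, 17 and 15 lists, and with a block by assay 2762, 2316 and 751 genes.

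Leader calls moved most. In place of 428 there were 816 with an offset of 15 nt, 116 with reads of a single position and no mismatch, 0 relative to leader mRNA by edgeR, 906 in the deposited 5' UTRs and 670 without the 15 nt next to the start codon. Without single libraries there were 41 to 657. The leader of AIM41 changed sign with a window of 50 nt (2.84), with reads of a single position (3.21) and in the deposited 5' UTR (6.4), and that of CHA1 relative to its mRNA (0.64). The fold of the leader share was 2.31 with 50 nt, 2.8 with the 15-nt offset and 2.74 with single positions and no mismatch. It was 2.6 without the 15 nt, 2.36 without the 20 leaders, 5.68 in the deposited 5' UTRs and 1.93 to 2.19 without single libraries. The deposited 5' UTRs are other regions, and for the rest the cause was not tested.

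Replicate SDs with at least 32 reads were 0.355, 0.416, 0.281 and 0.38 in the order of the text, as lower counts add counting error. The first codon position took 42.7% and 40.9% of footprints of 29 nt (rich, starved), 44.6% and 42.8% at 27 to 31 nt, and 36.3%, 34.3%, 36.9% and 35.8% of mRNA. Start density in rich footprints was 3.07 from pooled reads, 2.89 with at least 500 reads and 3.13 as a median. For mRNA it was 0.88 pooled and 0.85 as a median in rich medium and 0.92 with 500 reads and 0.9 as a median in starved cells. For both the cause was not tested.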

Other observations

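All tests of introns and of start triplets were chosen after the result was seen; those of the range of efficiencies were set before.

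Introns of ribosomal protein genes fell further than the mature mRNA. All 87 tested introns fell, with a median log2 change of -3.13, and their reads went from 8890.7 and 7800.2 per 1000000 coding reads (scaled by the TMM factor) in rich medium to 1335.9 and 1002.6 in starved cells. Of 17 introns of other genes 7 fell and 2 rose, with a median of -0.89, and their reads went from 327 and 302.3 to 282.2 and 235.1. By permutation of introns, not independent units, the sets differed (2-sided p = 1e-05, the floor of 100000 resamples).

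Footprints within leaders gathered most on ATG and TTG triplets. Among 28-nt footprints more than 15 nt upstream of the start codon, with at most 5 reads counted per position, ATG held 6.90 and 9.39 times the reads of an even spread over each leader in rich medium and 7.60 and 3.01 times in starved cells. TTG held 7.05 and 4.51 times in rich medium (95% bootstrap intervals from 4.303 to 10.126 and from 2.835 to 6.459) and 3.27 and 2.50 times in starved cells (from 2.28 to 4.198 and from 1.875 to 3.203). The 8 other triplets 1 base away from ATG held between 0.372 (ATC) and 2.91 (CTG) times in rich medium and between 0.732 (AGG) and 2.12 (GTG) times in starved cells. In mRNA from rich medium ATG held 0.715 and 0.914 times and TTG 0.989 and 1.16 times.

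The deeper fall of introns in ribosomal protein genes could reflect less transcription, with mature mRNA lagging behind over 20 min. Lower mature mRNA alone was argued against, since 32 of 32 introns lay below the change of their own coding sequence, with medians of -3.08 and -1.47. Of 17 other introns 12 lay below their coding sequences too, by less (medians -0.98 and -1.54, permutation p = 0.011). Lower recovery of all unspliced RNA may thus play a part. Faster splicing or faster decay of unspliced RNA in these genes was not tested and stays open, and less transcription, not tested either, is a hypothesis.

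Efficiencies spanned a narrower range in starved cells. Rich libraries thinned to the starved depth had a log2 SD of 1.36 over 4139 genes, from 1.357 before thinning, where the starved ones had 1.017. Thinning adds counting error, which widens a spread. A narrower range was thus hardly a possible outcome, and the comparison says little beyond that. Chance values of the rich libraries were argued against by pairs of libraries with none in common, in which the efficiency in rich medium correlated with the change by -0.47 and -0.609 across genes. Fragments of mRNA in the starved footprint libraries cannot be told apart from a change in translation, since the largest share that the 3' UTRs allow, 8.25%, lowered the rich SD to 1.077, near the starved value. The medium shift may narrow the range.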
